A study of Mus musculus with 12 samples.

How the data were processed

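The values were raw read counts per gene in 12 heart libraries, as deposited by the authors. Per the labels, RNA was extracted with Qiazol, and 300 ng of each sample were selected for poly(A) RNA and made into libraries with the TruSeq RNA kit v2, which keeps no strand. Sequencing on an Illumina HiSeq instrument gave single-end reads of 50 bp. Per the submitters' processing notes, reads were trimmed with fastp 0.20.0, aligned to GRCm38 with HISAT2 2.1.0 and counted with featureCounts 2.0.0, and edgeR 3.30.0 was used from there. The counts held no normalised values. Gene symbols came with 47224 of the 47729 genes, and positions and gene types were taken from GENCODE M21.

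Each sample was placed in 1 of 4 groups by its title. The titles of the control samples also carry the words Ang II control, and they were taken as the saline group that the design names. The labels give no batch, date or pairing. The groups, the comparisons, the gene lists, the rule for named genes and most alternative settings were fixed before the data were examined.

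Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed with filterByExpr, which left 15336, and libraries were scaled by TMM. A single model with a mean per group was fitted to all 12 libraries by robust quasi-likelihood, with a common biological coefficient of variation of 0.189. Contrasts were tested with the two-sided quasi-likelihood F test, and p-values were adjusted over all tested genes by Benjamini-Hochberg with a threshold of 0.05. Log2 CPM values, used for the list tests and scores, had a prior count of 2. Log2 fold changes came from the fitted model at its default prior count. The SE of an edgeR log2 fold change was its absolute value divided by the square root of the quasi-likelihood F statistic. It therefore restates that test and is not a separate estimate of the error. CPM values used TMM-scaled library sizes, and SD is over the 3 libraries of a group. A single gene compared by an exact permutation test of 3 against 3 libraries cannot reach a p below 0.1, so no such tests were used.

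Of 47 gene lists fixed from textbook knowledge, 46 had at least 5 tested genes. They cover the matrix, fibroblasts, cardiomyocytes, metabolism, hormone and receptor systems, inflammation, markers of other cell types and tissues, and stress responses. Camera in limma 3.58.1 compared each list with all other genes at a preset correlation between genes of 0.01, with Benjamini-Hochberg over the 46 lists of a comparison. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move one way on balance and compares them with no other genes. The members of each list were also adjusted over the list alone.

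Genes are named in the text by a fixed rule with 4 parts. For the comparison with calls, up to 8 higher and 8 lower genes were taken, with the largest log2 fold change among those past the threshold whose groups did not overlap and whose mean was at least 1 CPM, leaving out predicted genes and pseudogenes. Up to 4 genes with the smallest p were taken from each described list. A set of 17 genes was named in advance: Postn, Col1a1, Col3a1, Acta2, Nppa, Nppb, Myh7, Myh6, Ccn2, Tgfb1, Timp1, Agtr1a, Ace, Ren1, Pparg, Cnr2 and Il6. Ren1 had 19 reads over all libraries and was not tested. Genes called under Ang II and called in the opposite direction under a treatment were to be named as well, and there were 0 in edgeR, with 12 under EHP-101 and 80 under losartan among the 526 Ang II genes of DESeq2. One gene that the rule gives is not reported here. Of 146 named genes, 45 have exon bases in common with another annotated gene, and their levels are uncertain to that extent.

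Each alternative was run by itself. DESeq2 brought its own size factors, test and filter, and the fit with quality weights changed the tool and the weights together. The alternatives were RLE factors, library size alone, DESeq2 1.42.0, limma-voom, no filter on low counts, a mean of at least 5 CPM, the replicate number as a block, only the 2 groups compared, an absolute log2 fold change of at least 1, and each library left out in turn. An atrial marker score as a covariate and limma-voom with quality weights were added after seeing the data. DESeq2 gave no adjusted p for 899 genes in the comparison of Ang II with control, through its own filter. Where a left-out library leaves its group with 2 libraries, the spread is pooled over all groups.

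A self-test placed changes of known size in simulated counts, drawn from the observed mean levels and dispersions, for the comparison of Ang II with control alone. With 3 libraries against 3, 72 of 100 genes with a 2-fold change and 98 of 100 with a 4-fold change were called, with 4 false calls among the 15336 genes and 0 calls of the wrong sign. These counts held no outlying library and no correlation between genes. Data sets drawn from the fitted means called a median of 1172 genes for Ang II against control, where the real libraries gave 83. The shares may therefore overstate what the real libraries can detect. No pair of replicates agreed within sampling noise: the chi-square per degree of freedom was 11.55 to 144. Mitochondrial transcripts took 17.74% to 25.41% of the counts of a library, and the most abundant gene took 3.782% to 6.374% of a library. Retention of the Ang II differences was compared with 30 simulated data sets per setting, drawn from the fitted means and dispersions. Each gene was drawn independently of the others.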

Results

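RNA from mouse hearts was sequenced and counted per gene in 12 libraries, 3 in each of 4 groups. Male C57BL/6 mice of 8 weeks received saline or angiotensin II (Ang II), a peptide hormone that raises blood pressure and drives cardiac fibrosis, from subcutaneous pumps for 28 days. During the last 2 weeks of infusion, 1 Ang II group received vehicle, 1 received oral EHP-101 at 20 mg/kg and 1 received losartan at 0.6 g/L in its water. EHP-101 acts on the nuclear receptor PPARγ and the cannabinoid receptor CB2, and losartan blocks the Ang II receptor AT1. Total counts were 22155418 to 23766752 per library in the control group and 23585132 to 24040516 in the Ang II group. They were 22745721 to 23521895 under EHP-101 and 22574756 to 23730465 under losartan. Of 47729 annotated genes, 15336 had enough counts to be tested. The labels do not say whether the replicates were separate animals, so every p-value measures the spread between these samples, which may be technical. Means are per-million counts (CPM) with SD over n = 3 libraries, and errors of log2 fold changes are SE. Calls over all genes are those of edgeR where no other tool is named.

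Some libraries stood apart within their groups. Control replicate 2 lay at -84.37 on the first principal component, which carried 35.27% of the variance, while the other 11 libraries lay between -12.72 and 32.41. Its oxidative phosphorylation score, the mean log2 CPM of the list relative to all 12 libraries, was 0.86, against 0.1 and -0.02 in the other control libraries. The labels name the tissue as heart and do not say which part of it was sampled. Markers of atrial tissue varied between the libraries. Their scores were 0.78, -1.49 and 1.02 in the control libraries and 1.64, 1.12 and 0.87 in the Ang II libraries. They were -0.51, -1.25 and 0.6 under EHP-101 and -1.01, 0.77 and -2.53 under losartan. Bmp10, a growth factor made in the atria, had 356 ± 143 CPM in the Ang II group and 0.592 ± 0.50 CPM under losartan, with a log2 fold change of -9.25 ± 2.74 (adjusted p = 0.358, edgeR).

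The comparison of the Ang II and control groups asks what the infusion changed in the heart. Extracellular matrix genes were the strongest part of the answer. Cilp, a matrix glycoprotein of fibrotic tissue, rose from 47.7 ± 10.3 to 364 ± 53.7 CPM (7.62-fold, log2 fold change 2.93 ± 0.29). Tnc, the matricellular protein tenascin-C, rose 8.05-fold, and the network collagen Col8a1 rose 3.93-fold, from 45.9 ± 7.59 to 180 ± 34.2 CPM. Both had an adjusted p of 0.00176 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, as did Cilp. Lox and Loxl3, which crosslink collagen, rose 11.4-fold and 3.75-fold, and the thrombospondin Thbs4 rose 8.26-fold (adjusted p = 0.00435 for each). Postn, the activated fibroblast marker periostin, rose from 123 ± 4.57 to 732 ± 152 CPM (log2 fold change 2.58 ± 0.39, adjusted p = 0.015).

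In GRCm38 with GENCODE M21, Cilp (ENSMUSG00000042254) spans chromosome 9 from 65265180 to 65280605 and Tnc (ENSMUSG00000028364) chromosome 4 from 63959785 to 64047015. Col8a1 (ENSMUSG00000068196) lies on chromosome 16 from 57624258 to 57754737 and Loxl3 (ENSMUSG00000000693) on chromosome 6 from 83034173 to 83052562. Lox (ENSMUSG00000024529) lies on chromosome 18 from 52516067 to 52529867 and Thbs4 (ENSMUSG00000021702) on chromosome 13 from 92751590 to 92794818. Postn (ENSMUSG00000027750) lies on chromosome 3 from 54361109 to 54391037. Exons of Lox, Loxl3 and Tnc share bases with a gene on the other strand, and the library kit keeps no strand, so their levels are uncertain to that extent.

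The genes with the largest increases were low in the control hearts. Cthrc1, a secreted protein of injured tissue, rose from 0.466 ± 0.23 to 12.9 ± 4.88 CPM (28.2-fold, adjusted p = 0.015, edgeR). Igfbp2, a binding protein of insulin-like growth factors, rose 25-fold, and Sprr1a, a stress-induced gene of cardiomyocytes, rose 23.3-fold (adjusted p = 0.0318 and 0.0196). C1qtnf3 rose 22.6-fold, Col11a1 16.4-fold and the prolyl hydroxylase subunit P4ha3 9.66-fold (adjusted p = 0.0203, 0.019 and 0.0254). The log2 fold change of Igfbp2 went from 4.65 to 3.80 without Ang II replicate 3, and those of Col11a1 and P4ha3 from 4.03 and 3.27 to 4.69 and 4.08 without Control replicate 1. Of the 4 genes that fell, Scn4b, a sodium channel subunit, went from 62.2 ± 13.8 to 28.9 ± 5.74 CPM with a log2 fold change of -1.11 ± 0.22 (adjusted p = 0.048). Ano10 and Ift81 fell with log2 fold changes of -0.97 ± 0.16 and -0.61 ± 0.12 (adjusted p = 0.0203 and 0.048). The fourth, the predicted gene Gm34302, was named after its values were seen and had a log2 fold change of -1.56 ± 0.31 (adjusted p = 0.048).

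Matrix gene lists moved together. Of 28 matricellular and matrix glycoprotein genes, 9 rose over all genes and 27 adjusted over the list alone, with a median log2 fold change of 1.38. The list passed camera with an adjusted p of 2.09e-25, and had an adjusted p = 0.154 with an estimated correlation. Elastin, Eln, was among them (5.07-fold, adjusted p = 0.00987). Of 19 fibrillar and network collagens, 8 rose over all genes and 19 adjusted over the list alone (median 1.67, camera adjusted p = 7.55e-18, adjusted p = 0.181 with an estimated correlation). Col3a1 rose from 391.5 ± 127 to 1453 ± 462 CPM (adjusted p = 0.0235), Col5a2 rose 3.83-fold and Col12a1 7.91-fold (adjusted p = 0.0095 and 0.0196). Col1a1 had a log2 fold change of 1.80 ± 0.38 and did not pass over all genes (adjusted p = 0.0635, edgeR), except without Ang II replicate 2 (0.0382), with the atrial score (0.0477), in DESeq2 (0.000196) and with quality weights (0.00127). Markers of fibroblasts and of atrial tissue were higher in the same hearts. Of 16 fibroblast markers, 2 rose over all genes and 4 adjusted over the list alone (median 0.41, camera adjusted p = 7.64e-05, adjusted p = 0.324 with an estimated correlation). The 14 atrial markers had a median of 0.46, with 0 passing over all genes or adjusted over the list alone (camera adjusted p = 0.0317, adjusted p = 0.67 with an estimated correlation). The atrial call was lost without Control replicate 2, Ang II replicate 1 or Ang II replicate 2 (adjusted p = 0.666, 0.126 and 0.0644). With the atrial score in the model the mean difference of the matricellular genes went from 1.79 ± 0.289 to 1.55 ± 0.218 (SE), and that of the collagens from 1.73 ± 0.352 to 1.44 ± 0.273.

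Genes that process, degrade and signal to the matrix followed. Of 20 collagen processing and crosslinking genes, 5 rose over all genes and 12 adjusted over the list alone, including Adamts2 (2.4-fold) and Loxl1 (2.03-fold). That list had a median of 0.56 and a camera adjusted p of 3.57e-10 (adjusted p = 0.181 with an estimated correlation). Of 18 matrix proteases and inhibitors, 3 rose over all genes and 11 adjusted over the list alone (camera adjusted p = 4.21e-07, adjusted p = 0.159 with an estimated correlation). They included Mmp2 (3.07-fold, adjusted p = 0.00987), Mmp14 (2.39-fold, adjusted p = 0.0142) and Timp1, an inhibitor of metalloproteases (5.65-fold, adjusted p = 0.0299). The log2 fold change of Timp1 went from 2.50 to 1.84 without Ang II replicate 3. Of 15 myofibroblast markers, 3 rose over all genes and 12 adjusted over the list alone (median 1.32, camera adjusted p = 3.57e-10, adjusted p = 0.154 with an estimated correlation). Ltbp2, which binds fibrillin in the matrix, rose 6.97-fold, whereas smooth muscle actin, Acta2, had a log2 fold change of 0.70 ± 0.29 (adjusted p = 0.256). Of 21 TGF-beta signalling targets, 1 rose over all genes and 12 adjusted over the list alone (camera adjusted p = 3.38e-06, adjusted p = 0.154 with an estimated correlation). The gene was Tgfb3 (2.53-fold, adjusted p = 0.0406), while Tgfb1 itself had a log2 fold change of -0.04 ± 0.17 (adjusted p = 0.921) and Ccn2 one of 1.29 ± 0.35 (adjusted p = 0.132, and 0.0197 without losartan replicate 3).

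**Figure D1:**
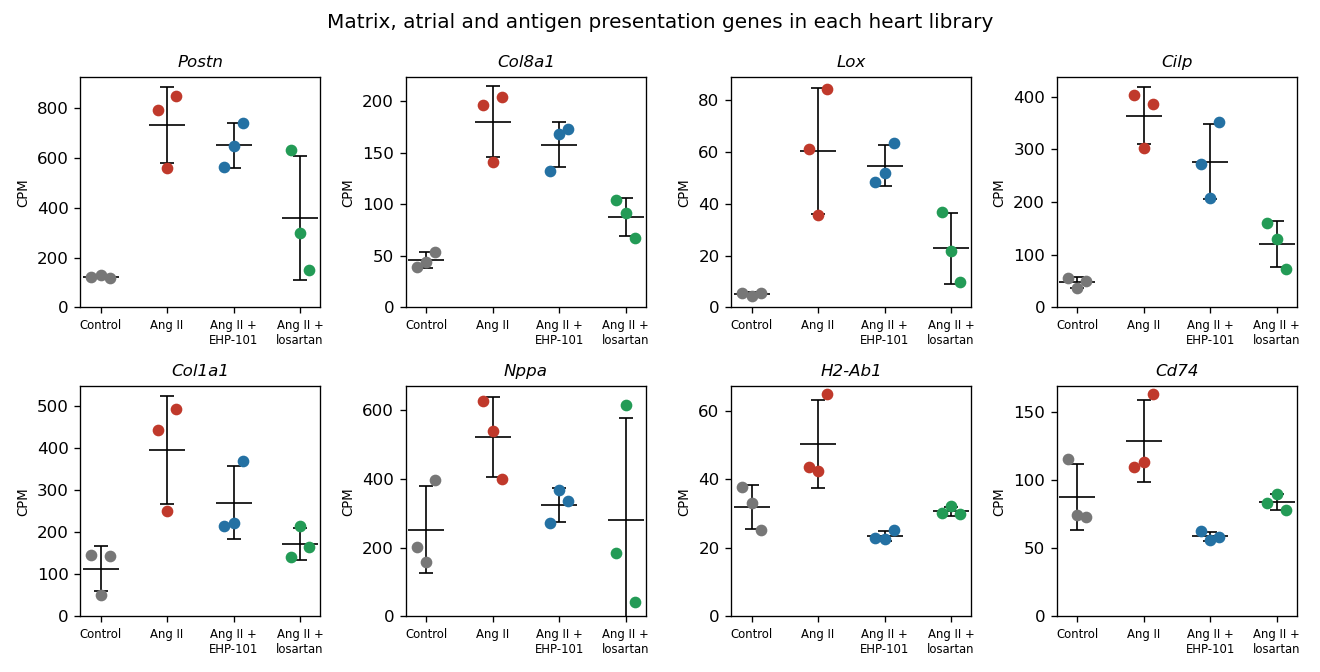
CPM (vertical axis) of 8 genes in the 12 libraries, by group (horizontal axis); points are libraries, and lines give the mean and SD of 3. Cilp stood at 47.7 in the control group, 364 in the Ang II group and 121 under losartan.

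Acute phase and antigen presentation genes were also higher. Of 22 IL6-JAK-STAT3 and acute phase genes, 3 rose over all genes and 7 adjusted over the list alone (camera adjusted p = 5.18e-06, adjusted p = 0.181 with an estimated correlation). The protease inhibitor Serpina3n rose 5.65-fold (adjusted p = 0.0334) and Socs3, a feedback inhibitor of cytokine signalling, rose 1.71-fold (adjusted p = 0.0436). Il6 had a log2 fold change of 3.71 ± 0.87 from few reads, 3 to 141 per library, and did not pass (adjusted p = 0.0933). It had 0.72, 0.66 and 5.28 CPM in the Ang II libraries, and without Ang II replicate 3 the log2 fold change was 2.03. Without Ang II replicate 2 it passed (adjusted p = 0.0416). Of 14 dendritic cell and antigen presentation genes, 0 passed over all genes in edgeR and 8 were higher adjusted over the list alone (median 0.65). That list had a camera adjusted p of 8.27e-07 (adjusted p = 0.24 with an estimated correlation). H2-Ab1, a class II histocompatibility chain, had a log2 fold change of 0.65 ± 0.18 (adjusted p = 0.13) and the dendritic cell receptor Cd209a one of 1.91 ± 0.45 (adjusted p = 0.0965, and 0.0248 without Ang II replicate 2).

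Metabolic and stress genes of the heart muscle were also examined. Of 38 nuclear subunits of oxidative phosphorylation, 0 passed over all genes in edgeR and 34 were lower adjusted over the list alone, with a median of -0.59. The list passed camera with an adjusted p of 7.11e-16 (adjusted p = 0.372 with an estimated correlation). Its median was -0.23 without Control replicate 2, the library with the highest score for these genes, and its adjusted p was then 3.57e-11. Uqcrc1, a core subunit of complex III, had a log2 fold change of -0.59 ± 0.18 (adjusted p = 0.155). Of 31 fatty acid oxidation genes, 16 were lower adjusted over the list alone and 0 over all genes in edgeR (median -0.46, camera adjusted p = 1.31e-09, adjusted p = 0.359 with an estimated correlation), among them Hadh with a log2 fold change of -0.61 ± 0.18. DESeq2 called 5 of these genes lower over all genes, Hadh among them (adjusted p = 0.0254), and 7 of the oxidative phosphorylation genes, and limma-voom called 0 in either list. Of 19 cardiac stress and fetal programme genes, 2 were higher adjusted over the list alone and 0 over all genes in edgeR. DESeq2 called 3 of them higher, among them Myh7 (adjusted p = 0.00259) and Ankrd1 (0.047), and limma-voom 0. Ankrd1 also passed in edgeR without Control replicate 2 (adjusted p = 0.0276). The list had a camera adjusted p of 0.00217 (adjusted p = 0.303 with an estimated correlation), which became 0.0712 without Control replicate 3, and its median of 0.41 became 0.69 without Control replicate 2. Myh7, the fetal myosin heavy chain, had 646 ± 174 CPM against 197 ± 97.5 (adjusted p = 0.108), and the natriuretic peptide Nppa, which the atria also make, 522 ± 115 against 252 ± 127 (adjusted p = 0.426).

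Of 13 genes of the renin-angiotensin-aldosterone system, 0 passed over all genes in edgeR and 1 was lower adjusted over the list alone (camera adjusted p = 0.533). It was Agtr1a, which encodes the main AT1 receptor, at 26.2 ± 4.98 CPM against 39.5 ± 0.387 in the control group (log2 fold change -0.60 ± 0.13, adjusted p = 0.0718, and 0.0199 without Ang II replicate 2). DESeq2 called 1 gene of this list lower over all genes, and limma-voom 0. The converting enzyme Ace had a log2 fold change of 0.61 ± 0.21 (adjusted p = 0.197). Myh6, Nppb, Pparg and Cnr2 had log2 fold changes of 0.06, -0.25, -0.27 and -0.05, with adjusted p values of 0.935, 0.868, 0.506 and 0.947. Nppb had 1111 CPM in Control replicate 2 against 139 and 116 in the other control libraries. Without Control replicate 2 its log2 fold change was 1.59 (adjusted p = 0.0899), and with quality weights, which gave that library little weight, it was 1.49 and passed (adjusted p = 0.00316).

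In total 83 genes passed at an adjusted p under 0.05 in edgeR, 79 of them higher and 4 lower. At an unadjusted p under 0.05 there were 2702, and the group values of 22.57% of the genes did not overlap, where chance gives 10%. DESeq2 called 526 genes, which included 80 of the 83, and limma-voom called 51. Scaling by library size alone moved the median log2 fold change of all genes by 0.17 and gave 89 higher genes and 1 lower, with adjusted p values of 0.0847, 0.0599 and 0.137 for Scn4b, Ano10 and Ift81. Single libraries moved the count: it was 25, 15 and 21 without Control replicates 1, 2 and 3, 8, 151 and 8 without Ang II replicates 1, 2 and 3, and 51 without EHP-101 replicate 1. Cilp, Tnc, Col8a1 and Loxl3 passed without any 1 of the 12 libraries, and Lox and Thbs4 did not pass only without Control replicate 2 (adjusted p = 0.0908 and 0.0898). Every other gene named here as having risen or fallen, Gm34302 aside, did not pass without Ang II replicate 1 or without Ang II replicate 3, Postn for example with adjusted p = 0.0626 and 0.0783. Of the 46 lists tested, 28 passed camera with the preset correlation, 22 higher and 6 lower, 0 passed with an estimated correlation, and 9 passed fry.

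The comparison of EHP-101 with Ang II alone asks which genes differed once the compound was added to the infusion. Genes of antigen presentation had the smallest p-values. H2-Ab1 (ENSMUSG00000073421, chromosome 17 from 34257689 to 34269419) had 23.5 ± 1.46 CPM under EHP-101 against 50.3 ± 12.7 (log2 fold change -1.10 ± 0.18, adjusted p = 0.291). Cd74, the invariant chain of class II histocompatibility complexes (ENSMUSG00000024610, chromosome 18 from 60803848 to 60812652), had 58.8 ± 3.32 CPM against 129 ± 30.1 (log2 fold change -1.13 ± 0.19). No single gene passed over all genes in edgeR, with 0 below an adjusted p of 0.05 and 1108 below an unadjusted p of 0.05.

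**Figure D2:**
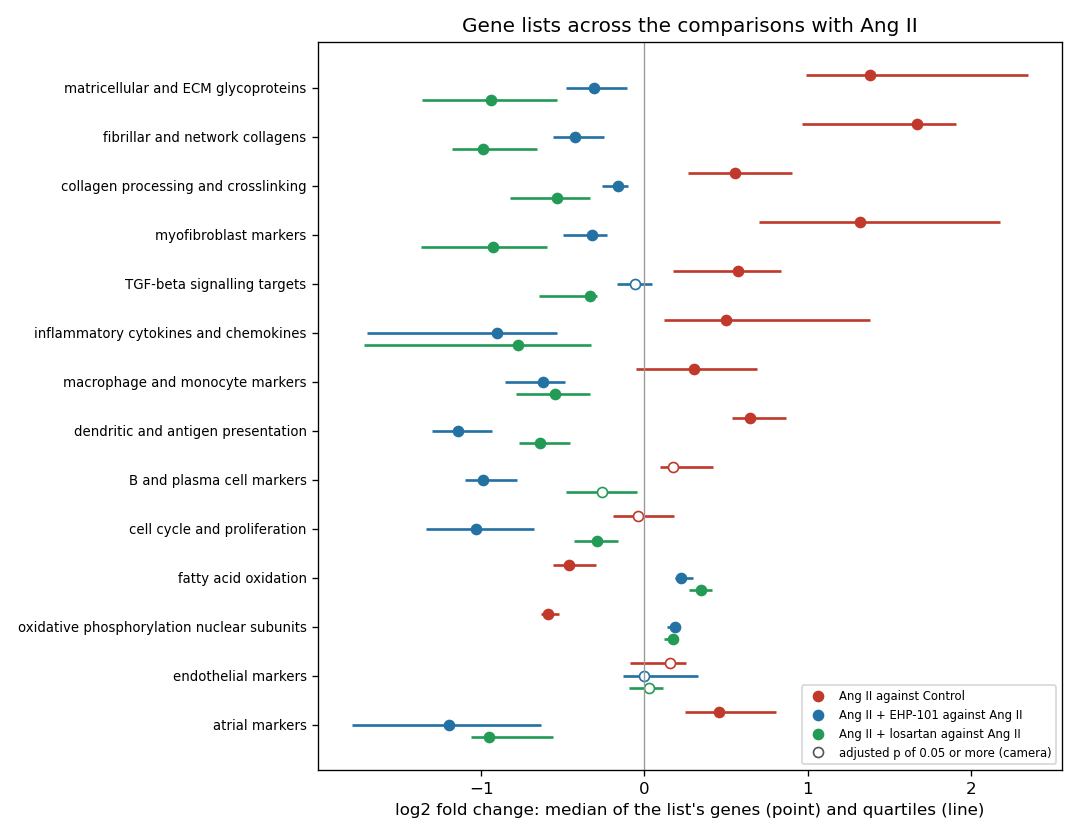
Median log2 fold change (point) and quartiles (line) on the horizontal axis for 14 gene lists on the vertical axis, in 3 comparisons; open circles are lists whose camera adjusted p is 0.05 or more. The matricellular genes had a median of 1.38 under Ang II, -0.31 with EHP-101 and -0.94 with losartan added.

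Leukocyte and cell division genes were lower as groups. Of 14 dendritic cell and antigen presentation genes, 11 were lower adjusted over the list alone and 0 over all genes (median -1.14, camera adjusted p = 1.36e-12, adjusted p = 0.182 with an estimated correlation). Of 30 cell cycle genes, 19 were lower adjusted over the list alone and 0 over all genes (median -1.03, camera adjusted p = 4.61e-21, adjusted p = 0.249 with an estimated correlation). Top2a, a topoisomerase of dividing cells, had 2.69 ± 1.46 CPM under EHP-101, 9.32 ± 3.91 with Ang II alone and 7.74 ± 3.03 in the control group. Of 26 inflammatory cytokines and chemokines, 12 were lower adjusted over the list alone and 0 over all genes (median -0.90, camera adjusted p = 2.86e-13, adjusted p = 0.177 with an estimated correlation). Il1b had a log2 fold change of -2.60 ± 0.62, the neutrophil chemokine Cxcl1 -1.80 ± 0.43 and the monocyte chemokine Ccl2 -1.56 ± 0.41.

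Of 28 macrophage and monocyte markers, 10 were lower adjusted over the list alone and 0 over all genes. The list had a median of -0.62 and a camera adjusted p of 1.36e-12 (adjusted p = 0.249 with an estimated correlation). Ccr2, a receptor of recruited monocytes, had 6.36 ± 2.35 CPM against 19.4 ± 8.55. Of 16 B and plasma cell markers, 7 were lower adjusted over the list alone and 0 over all genes (median -0.99, camera adjusted p = 1.38e-09, adjusted p = 0.29 with an estimated correlation). Ighm, the heavy chain of IgM, had 9.15 ± 3.5 CPM against 19.5 ± 4.99. Of 6 mast cell and eosinophil markers, 4 were lower adjusted over the list alone and 0 over all genes (camera adjusted p = 0.000174, adjusted p = 0.28 with an estimated correlation), Cpa3 for example with a log2 fold change of -1.66 ± 0.34. These 6 lists kept their camera calls without any 1 of the 12 libraries. Il1b was at -1.94 and the cytokine median at -0.54 without Ang II replicate 3, Cxcl1 was at -2.47 without EHP-101 replicate 3, and the B cell median -0.65 without EHP-101 replicate 2. Macrophage markers were also lower under losartan than with Ang II alone (mean log2 difference -0.534 ± 0.215 SE, camera adjusted p = 7.22e-08). Between EHP-101 and losartan the mean differed by -0.16 ± 0.215 for macrophage markers and -0.128 ± 0.205 for cytokines, within 2 SE of 0. So did antigen presentation genes (-0.275 ± 0.186), B and plasma cell markers (-0.593 ± 0.336) and mast cell and eosinophil markers (-0.472 ± 0.274). Of the 6 lists, only the cell cycle genes lay beyond 2 SE, at -0.766 ± 0.342.

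Matrix genes were lower by less. The 19 collagens had a median log2 fold change of -0.43, with 0 passing over all genes or adjusted over the list alone (camera adjusted p = 0.00055, adjusted p = 0.545 with an estimated correlation). Col3a1 had 756 ± 201 CPM against 1453 ± 462 (log2 fold change -0.94 ± 0.31, adjusted p = 0.473), and Col1a1 a log2 fold change of -0.55 ± 0.37. The 28 matricellular genes had a median of -0.31, with 0 passing over all genes or adjusted over the list alone (camera adjusted p = 0.00531, adjusted p = 0.571 with an estimated correlation). Tnc had a log2 fold change of -0.88 ± 0.29, and Postn had 650 ± 90.1 CPM against 732 ± 152 (log2 fold change -0.17 ± 0.37, adjusted p = 0.979). Without Ang II replicate 3 or EHP-101 replicate 1 the matricellular list had an adjusted p of 0.194 or 0.0752 and a median of -0.09 or -0.20. Atrial markers were lower in the same libraries (median -1.20, camera adjusted p = 4.5e-05, adjusted p = 0.477 with an estimated correlation, 0 of 14 passing over all genes or adjusted over the list alone). With the atrial score in the model the adjusted p was 0.872 for the collagens, with a median of -0.06, and 0.632 for the matricellular genes. With that score the antigen presentation and cell cycle lists still passed (1.93e-08 and 9.21e-26), although the atrial scores of the Ang II and EHP-101 libraries did not overlap.

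Clock genes and steroid-responsive genes were higher. Of 19 circadian clock genes, 5 were higher and 2 lower adjusted over the list alone, and 0 passed over all genes (median 0.55, camera adjusted p = 8.99e-05, adjusted p = 0.182 with an estimated correlation). Per2, a repressor in the clock, had 26.1 ± 4.96 CPM against 6.52 ± 0.38 (4-fold, adjusted p = 0.312). Of 15 glucocorticoid-responsive genes, 1 was higher adjusted over the list alone and 0 over all genes (camera adjusted p = 1.13e-05, adjusted p = 0.452 with an estimated correlation). Fkbp5, a chaperone partner of the steroid receptor, had 36.0, 238.71 and 27.2 CPM in the 3 EHP-101 libraries against 19.6 ± 0.406 with Ang II alone. The median of these genes was 0.27 without EHP-101 replicate 2 (camera adjusted p = 0.0289).

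Genes linked to the compound's receptors were also examined: targets of PPAR, and receptors and enzymes of the endocannabinoid system. No list of CB2 targets was tested. Of 28 PPAR alpha and gamma targets, 0 passed over all genes or adjusted over the list alone (median 0.22, camera adjusted p = 0.00151, adjusted p = 0.452 with an estimated correlation). Without EHP-101 replicate 1 the camera value was 0.0634 and the median 0.119, and the median was 0.36 without Ang II replicate 2. The lipid droplet gene Plin4 had a log2 fold change of 0.80 ± 0.25 and lipoprotein lipase, Lpl, 0.44 ± 0.17, while Pparg itself had 0.34 ± 0.21 (adjusted p = 0.855). Of 8 endocannabinoid system genes, 0 passed over all genes or adjusted over the list alone (median -0.06, camera adjusted p = 0.933). Cnr2, which encodes CB2, was read 13 to 35 times per library and had 0.819 ± 0.31 CPM against 1.15 ± 0.24 (adjusted p = 0.873).

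For this comparison DESeq2 called 63 genes, including H2-Ab1 and Cd74 (adjusted p = 0.000197 for each), and limma-voom called 0. The DESeq2 genes included 6 lower genes of antigen presentation, 4 of the cytokine list, 3 macrophage markers and 3 higher clock genes. Only 1 of 30 cell cycle genes, 1 of 6 mast cell and eosinophil markers and 0 of 16 B and plasma cell markers were among them. Group values did not overlap for 16.75% of the genes, against 10% by chance, and library size scaling moved the median of all genes by -0.149. In camera 28 of 46 lists passed, 9 higher and 19 lower, whereas 0 passed with an estimated correlation and 2 passed fry.

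The comparison of losartan with Ang II alone asks what blocking the AT1 receptor changed during continued infusion. Matrix genes were lower as groups than with Ang II alone. Cilp had 121 ± 44.1 CPM under losartan against 364 ± 53.7 (log2 fold change -1.59 ± 0.28) and Thbs4 47.0 ± 26.5 against 158 ± 42.3 (log2 fold change -1.75 ± 0.35), each with an adjusted p of 0.166 in edgeR. Col8a1 had 87.7 ± 18.5 CPM against 180 ± 34.2 (log2 fold change -1.04 ± 0.20), and Loxl3 15.0 ± 3.3 against 33.6 ± 8.25 (log2 fold change -1.17 ± 0.23). The smallest p-value belonged to Smad6, an inhibitor of BMP and TGF-beta signalling (ENSMUSG00000036867, chromosome 9 from 63953076 to 64022059), with 7.34 ± 0.551 CPM against 15.1 ± 2.52 (adjusted p = 0.123). Without Control replicate 2, Smad6 passed with an adjusted p of 0.036.

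Of 28 matricellular genes, 22 were lower adjusted over the list alone and 0 over all genes. The list had a median of -0.94 and a camera adjusted p of 1.51e-19 (adjusted p = 0.141 with an estimated correlation). Of 20 collagen processing genes, 14 were lower adjusted over the list alone and 0 over all genes (median -0.53, camera adjusted p = 9.74e-14, adjusted p = 0.12 with an estimated correlation), P4ha3 for example with a log2 fold change of -2.27 ± 0.51. Of 19 collagens, 11 were lower adjusted over the list alone and 0 over all genes (median -0.99, camera adjusted p = 2.77e-12, adjusted p = 0.243 with an estimated correlation). Col1a1 had 173 ± 38.0 CPM and Col3a1 646 ± 168, with log2 fold changes of -1.19 ± 0.37 and -1.17 ± 0.31. Of 15 myofibroblast markers, 7 were lower adjusted over the list alone and 0 over all genes (median -0.93, camera adjusted p = 1.16e-09, adjusted p = 0.12 with an estimated correlation). Ltbp2 had a log2 fold change of -1.76 ± 0.38 and Postn -1.03 ± 0.37. Of 21 TGF-beta targets, 5 were lower adjusted over the list alone and 0 over all genes (median -0.33, camera adjusted p = 2.97e-08, adjusted p = 0.12 with an estimated correlation). Timp1 had 8.69 ± 3.31 CPM under losartan, a log2 fold change of -1.90 ± 0.43 (adjusted p = 0.226), which was -1.23 without Ang II replicate 3. Postn was at -1.72 without losartan replicate 1.

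Atrial markers were lower under losartan as well (median -0.95, camera adjusted p = 2.43e-06, adjusted p = 0.342 with an estimated correlation, 0 of 14 passing over all genes or adjusted over the list alone). With the atrial score in the model the matricellular and collagen lists still passed camera (adjusted p = 2.01e-06 and 0.00182), with a matricellular median of -0.56. The atrial scores of the Ang II and losartan libraries did not overlap, so this fit rests on slopes within groups. The mean difference of the collagens went from -1 ± 0.352 to -0.437 ± 0.321 (SE), which is within 2 SE of 0. Of the 26 lists that passed for losartan, 16 kept their call and direction with that score, 8 lost the call, and 3 had the opposite direction, the atrial markers among the lost and the oxidative phosphorylation and epicardial genes past the threshold (adjusted p = 0.0229 and 0.00122). The atrial median was -0.59, -2.07 and -0.46 without losartan replicates 1, 2 and 3.

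Inflammatory and early response genes were lower under losartan. Of 26 cytokines and chemokines, 10 were lower adjusted over the list alone and 0 over all genes (median -0.77, camera adjusted p = 2.03e-10, adjusted p = 0.12 with an estimated correlation). Cxcl1 had a log2 fold change of -2.21 ± 0.44 and the B cell chemokine Cxcl13 -3.11 ± 0.77. Of 14 dendritic cell and antigen presentation genes, 6 were lower adjusted over the list alone and 0 over all genes (median -0.64, camera adjusted p = 7.56e-07, adjusted p = 0.228 with an estimated correlation). H2-Ab1 had 30.6 ± 1.26 CPM, a log2 fold change of -0.72 ± 0.18. The mean difference of the antigen presentation genes went from -0.566 ± 0.186 to -0.429 ± 0.236 (SE) with the atrial score, which is within 2 SE of 0. Of 26 immediate early genes, which respond within minutes to stimulation, 4 were lower adjusted over the list alone and 0 over all genes (median -0.42, camera adjusted p = 1.22e-06, adjusted p = 0.228 with an estimated correlation). Junb had a log2 fold change of -1.23 ± 0.30 and Fos -2.03 ± 0.54. Fos was at -1.12 without Ang II replicate 1 and Cxcl13 at -4.08 or -2.52 without losartan replicate 1 or 3. Without Ang II replicate 3 the cytokine and antigen presentation medians were -0.51 and -0.41.

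Fatty acid oxidation genes were higher, with a median of 0.35 and 0 of 31 passing over all genes or adjusted over the list alone (camera adjusted p = 1.44e-11, adjusted p = 0.265 with an estimated correlation). Ehhadh, a peroxisomal enzyme, had a log2 fold change of 0.78 ± 0.25 and the acyl-CoA dehydrogenase Acadm 0.44 ± 0.16. The 30 cell cycle genes had a median of -0.29, with 0 passing over all genes or adjusted over the list alone (camera adjusted p = 0.013, adjusted p = 0.609 with an estimated correlation). The camera value was 0.45 without Ang II replicate 3, 0.154 without losartan replicate 1 and 0.069 without losartan replicate 2, and the median was -0.06 without Ang II replicate 3 and -0.18 without losartan replicate 1. Of 13 renin-angiotensin genes, 0 passed over all genes or adjusted over the list alone (median -0.08, camera adjusted p = 0.97), and Agtr1a had a log2 fold change of 0.27 ± 0.13 (adjusted p = 0.622).

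For losartan against Ang II alone edgeR called 0 genes over all genes, with 1289 at an unadjusted p under 0.05 and 3 without Control replicate 2. DESeq2 called 106 genes, 5 of them higher and the rest lower, with Cilp at an adjusted p of 6.85e-05, and limma-voom called 0. The DESeq2 genes included 7 collagens, 6 collagen processing genes and 5 matricellular genes. The groups did not overlap for 19.67% of the genes, against 10% by chance, and library size scaling moved the median of all genes by -0.118. Of the 46 lists, 26 passed camera, 5 higher and 21 lower, with 0 under an estimated correlation and 5 in fry.

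**Figure D3:**
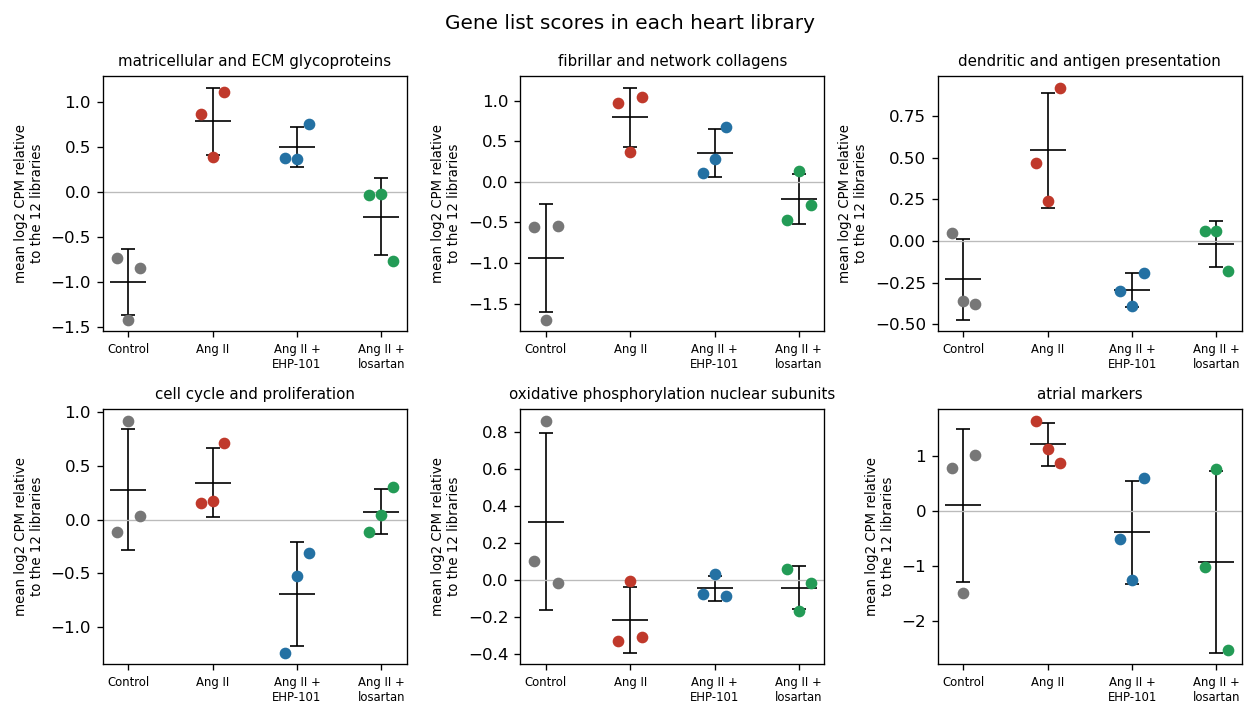
Scores of 6 gene lists (mean log2 CPM relative to the 12 libraries, vertical axis) by group (horizontal axis); points are libraries, and lines give the mean and SD of 3. Control replicate 2 had an oxidative phosphorylation score of 0.86, and the cell cycle scores under EHP-101 were -1.24, -0.53 and -0.31.

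The comparison of EHP-101 with losartan asks where the 2 treatments differed. Matrix genes were higher under EHP-101. Thbs4 had 142 ± 39.7 CPM under EHP-101 against 47.0 ± 26.5 under losartan (log2 fold change 1.6 ± 0.35, adjusted p = 0.472), and Cilp 277 ± 72 against 121 ± 44.1 (log2 fold change 1.20 ± 0.28, adjusted p = 0.506). Smad6 had 13.5 ± 0.77 CPM against 7.34 ± 0.551 (log2 fold change 0.88 ± 0.15, adjusted p = 0.196, edgeR). Of 28 matricellular genes, 2 were higher adjusted over the list alone and 0 over all genes (median 0.62, camera adjusted p = 5.59e-14, adjusted p = 0.285 with an estimated correlation). Of 20 collagen processing genes, 3 were higher adjusted over the list alone and 0 over all genes (camera adjusted p = 8.58e-11, adjusted p = 0.285 with an estimated correlation), Lox for example with 54.8 ± 7.85 CPM against 22.8 ± 13.6. Of 19 collagens, 6 were higher adjusted over the list alone and 0 over all genes (median 0.38, camera adjusted p = 8.88e-06, adjusted p = 0.479 with an estimated correlation). Col8a1 had 158 ± 21.9 CPM against 87.7 ± 18.5, and the collagen median was 0.17 without losartan replicate 1. Of 21 TGF-beta targets, 3 were higher adjusted over the list alone and 0 over all genes (camera adjusted p = 1.91e-08, adjusted p = 0.156 with an estimated correlation), among them Tgfb2 with a log2 fold change of 0.77 ± 0.20.

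By camera at the preset correlation, cell division genes were lower and stress genes higher under EHP-101 than under losartan. The 30 cell cycle genes had a median of -0.74, with 0 passing over all genes or adjusted over the list alone (camera adjusted p = 3.52e-14, adjusted p = 0.285 with an estimated correlation). Mki67, a marker of dividing cells, had a log2 fold change of -1.25 ± 0.47. The 19 cardiac stress genes had a median of 0.54, with 0 passing over all genes or adjusted over the list alone (camera adjusted p = 3.41e-07, adjusted p = 0.156 with an estimated correlation). Their median was 0.20 without EHP-101 replicate 2. Myh7 had 1299 ± 367 CPM under EHP-101 against 591 ± 287 under losartan (log2 fold change 1.14 ± 0.42, adjusted p = 0.744). Of 26 heat shock and protein folding genes, 2 were higher adjusted over the list alone and 0 over all genes (camera adjusted p = 1.82e-08, adjusted p = 0.285 with an estimated correlation). Hspa1a and Hspa1b, near-identical copies whose reads are hard to tell apart, had log2 fold changes of 1.82 ± 0.36 and 1.15 ± 0.31.

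Between the treatments edgeR called 0 genes, with 927 at an unadjusted p under 0.05 and 2 without Control replicate 2, while DESeq2 called 26 and limma-voom 0. Group values did not overlap for 13.31% of the genes, against 10% by chance. Camera passed 20 lists, 14 higher and 6 lower, with 0 under an estimated correlation and 0 in fry. The 79 genes that rose under Ang II were examined as a set. The contrast that gave them uses none of these 6 libraries, although the filter and the dispersions of the fit are shared by all 12, so the choice of the set is not fully independent of them. Of these, 76 had higher and 3 lower mean levels under EHP-101 than under losartan, with a median log2 difference of 0.73. As a set they passed camera with p = 3.56e-43, camera with p = 0.0197 under an estimated correlation of 0.505, and fry with p = 0.0117.

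The comparisons with the control group ask what remained different from saline under each treatment. Under EHP-101, 61 genes passed in edgeR, 46 higher and 15 lower. Lox had a log2 fold change of 3.37, Cilp 2.54, Postn 2.40 and Myh7 2.72, with adjusted p values of 0.00822, 0.00503, 0.0269 and 0.0269. Lower genes included Folr2, a marker of resident macrophages (-1.42, adjusted p = 0.0367), and the replication licensing genes Mcm5 and Mcm2 (-1.34 and -1.27, adjusted p = 0.0424 and 0.0338). These examples were chosen after their values were seen. Cilp passed in each of the 12 fits that left out 1 library, Lox in 9, Postn and Myh7 in 6, Mcm5 and Mcm2 in 2 and Folr2 in 1. At an unadjusted p under 0.05 there were 2593 genes, the groups did not overlap for 21.13% of the genes against 10% by chance, and DESeq2 called 495 and limma-voom 45. With the replicate number as a block edgeR called 36. With library size scaling 21 genes were higher and 1 lower. The count was 5, 35 and 5 without Control replicates 1, 2 and 3 and 22, 12 and 9 without EHP-101 replicates 1, 2 and 3. It was 27, 40 and 32 without Ang II replicates 1, 2 and 3 and 28 without losartan replicate 2. Under losartan 0 genes passed against the control group in edgeR, with 1640 at an unadjusted p under 0.05, 22 in DESeq2 and 0 in limma-voom, and the groups did not overlap for 15.36% of the genes.

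Of the genes called against the control group, 28 were higher and 3 lower both with Ang II alone and with EHP-101. The lower genes were Scn4b, Ano10 and Ift81. Both comparisons use the same control libraries, and 3 libraries cannot be divided so that each part keeps a pair. Over all tested genes the covariance of the log2 fold changes was 0.1467 between Ang II and EHP-101 and 0.1049 between Ang II and losartan. In simulated data with the same shared controls and no group difference these were 0.04787 (0.04515 to 0.05298) and 0.04732 (0.04252 to 0.05388). Where both treatments equalled Ang II alone they were 0.2701 (0.2591 to 0.2789) and 0.272 (0.2611 to 0.2805). Genes were drawn independently in these data sets, so the ranges are narrower than correlated genes would give.

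How far each treatment moved the 83 Ang II genes back was measured as well. Under losartan all 83 had a change opposite to that of Ang II, 76 of them at an unadjusted p under 0.05, and the median gene kept 38.3% of its difference from the control group. Under EHP-101, 75 of the 83 had an opposite change, 16 at an unadjusted p under 0.05, and the median gene kept 80.5%. In edgeR 0 of these changes passed over all genes for either treatment. Among its own 526 Ang II genes, DESeq2 called 80 in the opposite direction under losartan and 12 under EHP-101. Because the Ang II libraries serve in both differences, some return is built in. In 30 simulated data sets in which both treatments equalled Ang II alone, the retained share had a median of 92.58% (89.35 to 98.25) for losartan and 92.62% (88.05 to 97.9) for EHP-101. In data sets in which no group differed it was 51.5% and 51.0%. Where the treatments equalled Ang II alone, a median of 13 genes (7 to 19) had an opposite change at an unadjusted p under 0.05 for EHP-101, a range that holds the observed 16, and 12.5 (7 to 18) for losartan. The number with an opposite sign was then 55 (45 to 63) for EHP-101 and 55 (45 to 65) for losartan. The observed 75 and 83 lie above those ranges. Simulated genes were drawn independently, whereas the 79 genes higher under Ang II had an estimated correlation of 0.505 as a set. With such correlation the simulated ranges here are too narrow, so no conclusion is drawn from a value outside them. Where no group differed, 77 (73 to 80) and 77 (70 to 83) had an opposite sign, and 33 (20 to 40) and 31 (23 to 43) did so at an unadjusted p under 0.05. Neither kind of data set matched the observed 83 genes called for Ang II against control. Where no group differed 0 to 1 were called, and where the treatments equalled Ang II alone the median was 1172 (1079 to 1313).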

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

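No test of this part was chosen after its result was seen. All 4 gene lists below were singled out because camera gave them opposite directions under the 2 treatments, each relative to Ang II alone. Camera also had to find a difference between EHP-101 and losartan. Their medians had opposite signs as well. With 3 libraries in a group, a test for a single stray value within a group was not applied.

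Cardiac stress and fetal programme genes differed between the treatments with a camera adjusted p of 3.41e-07 (adjusted p = 0.156 with an estimated correlation). Their median log2 fold change against Ang II alone was 0.26 under EHP-101 (adjusted p = 0.133) and -0.32 under losartan (adjusted p = 0.00104), and the median between the treatments was 0.54. The mean score of these genes was 0.31 with Ang II alone, 0.31 under EHP-101 and -0.3 under losartan. By that measure only losartan differed from Ang II alone. Heat shock and protein folding genes differed with an adjusted p of 1.82e-08 (adjusted p = 0.285 with an estimated correlation), with medians of 0.08 under EHP-101 and -0.23 under losartan (adjusted p = 0.0339 and 0.000704). The value under EHP-101 was 0.266 without EHP-101 replicate 1, 0.0814 without EHP-101 replicate 2, and 0.0571, 0.175 and 0.0641 without Ang II replicate 1, Ang II replicate 2 and Control replicate 2.

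Cytosolic ribosomal protein genes differed with an adjusted p of 0.00827 (adjusted p = 0.874 with an estimated correlation), with medians of 0.04 under EHP-101 and -0.09 under losartan, neither past the threshold (adjusted p = 0.301 and 0.141). That difference was lost without losartan replicate 2 or 3 and without EHP-101 replicate 2 (adjusted p = 0.171, 0.223 and 0.0772). Hypoxia and HIF target genes differed with an adjusted p of 0.0162 (adjusted p = 0.285 with an estimated correlation), with medians of 0.11 and -0.02 (adjusted p = 0.0598 and 0.619).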

How the results depend on the processing

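The fits with the atrial score and with quality weights were chosen after seeing the data. Of 5267 alternative values of 242 named results, 4863 kept their direction and their side of the threshold, 182 lost a call, 170 gained one and 52 turned sign. These values cover Ang II against control, each treatment against Ang II alone, and EHP-101 against losartan. All 182 losses among them were in Ang II against control, the only one with called genes. In that comparison 1169 values were kept, 70 gained a call and 20 turned sign. In the others a gene that stayed uncalled counts as kept, and no loss was possible. They gave 1402, 1377 and 915 of the kept values, so the pooled count does not measure how robust the calls are. Of the genes named for EHP-101 against control, Postn and Myh7 lost their calls without a filter, Myh7, Folr2, Mcm5 and Mcm2 with library size alone, and Mcm5 in limma-voom and in the blocked fit. They were not followed in the fit of only those 2 groups. RLE factors and an absolute log2 fold change of at least 1 kept every total count of genes within 1.5 times. The latter left 2 of the 4 lower genes of Ang II against control and 9 of the 15 of EHP-101 against control, and RLE factors gave 6 lower genes in the former. Where no reason is given, the cause was not tested. Cnr2 and Il6 had few reads, 294 and 238 in all, and whether depth limited their tests was not examined.

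Genes called for Ang II against control numbered 526 in DESeq2, 51 in limma-voom, 167 without a filter, 2617 with quality weights and 20 with only these 2 groups, a fit with fewer samples. EHP-101 against Ang II had 63 in DESeq2, 10 without a filter and 3 with only these 2 groups. Losartan against Ang II had 106 in DESeq2, 30 without a filter, 598 with quality weights and 1 with only these 2 groups. EHP-101 against losartan had 26, 3 and 1 in DESeq2, without a filter and with quality weights. EHP-101 against control had 22 with library size alone, 495 in DESeq2, 158 without a filter, 275 with the atrial score, 477 with quality weights and 14 with only these 2 groups. Losartan against control had 22 in DESeq2 and 3 with quality weights. Quality weights gave Control replicate 1 a weight of 3.86 and Control replicate 2 one of 0.112. Ang II genes called in the opposite direction numbered 12 in DESeq2 and 2 without a filter for EHP-101, and 80, 21 and 459 in DESeq2, without a filter and with quality weights for losartan.

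With the replicate number as a block, 36 genes were called for EHP-101 against control. The 3 pairs of control and EHP-101 libraries with the same number all correlated above 0.1 (0.2212, 0.2259 and 0.1004). Of all 18 pairs of libraries with the same number, 5 correlated above 0.1 after group means were removed (-0.327 to 0.3299), and 6 of 12 libraries were closest to their own number, so the samples were not taken as paired over the 4 groups. For Ang II against control the blocked fit lost the calls of Igfbp2 (adjusted p = 0.0638), Ift81 (0.085), Timp1 (0.0971), Ddah1 (0.0611), Serpina3n (0.105) and Socs3 (0.0799). In the blocked fit Nppb had a log2 fold change of 0.25 for Ang II against control.

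Lists past camera for Ang II against control numbered 0 with an estimated correlation and 9 in fry. For EHP-101 against Ang II they numbered 15 with the atrial score, of which 13 were among the 28 and 2 were not. The other 15 of the 28 lost the call, 6 of them with the opposite direction. They numbered 0 with an estimated correlation and 2 in fry. For losartan against Ang II these were 0 and 5, and for EHP-101 against losartan 0 and 0, with an estimated correlation and in fry.

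Sign changes were in genes that did not pass in the edgeR fit of all libraries. For Ang II against control, Nppb (-0.25) was 0.063 with library size alone, 0.52 in limma-voom, 0.81 with the atrial score and 1.49 with quality weights. Tgfb1 (-0.04) was 0.16 with library size alone, 0.006 at 5 CPM, 0.061 with the atrial score and 0.20 with quality weights. Cnr2 (-0.05) was 0.13 with library size alone and 0.06 with the atrial score, and Myh6 (0.06) was -0.033 with the atrial score and -0.20 with quality weights. For EHP-101 against Ang II, library size alone gave -0.009 for Myh6, -0.009 for Ace and -0.004 for Mgll, each positive before, and quality weights gave -0.005 for Ace. The atrial score turned Nppa from -0.68 to 0.51 and Nppb from 0.27 to -0.54. For losartan against Ang II it turned Myh7 from -0.13 to 0.63 and Stard10 from -1.01 to 0.081. For EHP-101 against losartan, Myh6 (0.011) was -0.029 with library size alone, -0.054 with the atrial score and -0.10 with quality weights. Quality weights also gave -0.037 for Col3a1, -0.015 for Tgfb1 and 0.009 for Agtr1a there.

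Leaving out 1 library in turn gave 8 to 151 genes for Ang II against control, 5 to 62 for EHP-101 against control, 0 to 3 for losartan against Ang II, 0 to 2 for EHP-101 against losartan, and 0 to 2 Ang II genes called in the opposite direction under losartan. Log2 fold changes that turned sign ranged as follows. For Ang II against control, Cnr2 went from -0.194 to 0.132, Nppb from -0.693 to 1.588, Myh6 from -0.265 to 0.37 and Tgfb1 from -0.135 to 0.179. For losartan against Ang II, Myh7 went from -0.524 to 0.189, Myh6 from -0.006 to 0.308 and Ccn2 from -0.872 to 0.06. For EHP-101 against Ang II, Ace went from -0.099 to 0.336 and Napepld from -0.118 to 0.53. For EHP-101 against losartan, Myh6 went from -0.167 to 0.147, Pparg from -0.198 to 0.222, Tgfb1 from -0.045 to 0.112, Agtr1a from -0.1 to 0.039, Il6 from -0.091 to 0.914, Nppa from -0.297 to 1.519 and Acta2 from -0.503 to 0.01.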

Other observations

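The tests of the atrial covariate, of cardiomyocyte and fibroblast RNA and of the low-atrial libraries were chosen only after the result was seen. The length test and the splits of the samples were written beforehand.

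Nerve and glial genes were higher under Ang II and lower under both treatments. The 14 Schwann and neuronal markers were higher under Ang II (median 0.69, camera adjusted p = 0.00103, adjusted p = 0.384 with an estimated correlation), with 0 passing over all genes and 4 adjusted over the list alone. Their median was 0.429 without Control replicate 2. Under EHP-101 their median was -0.54 against Ang II alone, with 0 passing over all genes and 1 lower adjusted over the list alone (camera adjusted p = 0.00173, adjusted p = 0.452 with an estimated correlation). That call was lost without Ang II replicate 1 (adjusted p = 0.109). Under losartan they were lower than with Ang II alone (median -0.72, camera adjusted p = 6.19e-05, adjusted p = 0.279 with an estimated correlation), with 0 passing over all genes and 1 adjusted over the list alone, and the median was -0.46 without Ang II replicate 1. The gene was Tubb3, a tubulin of neurons, with a log2 fold change of -1.49 ± 0.28 (adjusted p = 0.166, edgeR). The list did not pass between EHP-101 and losartan (median -0.03, adjusted p = 0.313). With the atrial score it did not pass against Ang II alone under either treatment (adjusted p = 0.744 and 0.732). Of 21 complement and coagulation genes, 5 were higher under Ang II adjusted over the list alone and 0 over all genes (median 0.70, camera adjusted p = 0.000352, adjusted p = 0.384 with an estimated correlation). Without Control replicate 2, whose score was -0.95 against 0.05 and -0.06 in the other controls, that median was 0.421.

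Matrix proteases and fuel genes shifted under EHP-101. Of 18 matrix proteases and inhibitors, 6 were lower than with Ang II alone adjusted over the list alone and 0 over all genes (median -0.32, camera adjusted p = 0.00055, adjusted p = 0.29 with an estimated correlation). The 31 fatty acid oxidation genes had a median of 0.22, with 0 passing over all genes or adjusted over the list alone (camera adjusted p = 4.03e-07, adjusted p = 0.452 with an estimated correlation). The 13 T and NK cell markers had a median of -0.77, with 0 passing over all genes or adjusted over the list alone (camera adjusted p = 0.00022, adjusted p = 0.249 with an estimated correlation). Endothelial markers had a median of -0.00 and did not pass (adjusted p = 0.344). Ribosomal protein genes had a median of -0.31 under Ang II against control (camera adjusted p = 0.00103, adjusted p = 0.713 with an estimated correlation). Without Control replicate 2 that median was 0.109, with an adjusted p of 0.0125 in the opposite direction. Epicardial and mesothelial markers had a median of 0.69 in that comparison, and their adjusted p of 0.019 (adjusted p = 0.601 with an estimated correlation) became 0.37 without Control replicate 2. Without that library the cell cycle genes, with an adjusted p of 0.95 over all libraries, had a median of 0.481 and an adjusted p of 0.00315.

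Leukocyte, antigen presentation and cell cycle genes were lower under EHP-101 than under Ang II alone, by a mean log2 difference of -0.838 ± 0.139 (SE). A smaller share of atrial and epicardial tissue in the pieces would make the difference vanish once the atrial score is held fixed. As a set it kept 105% of its size, at -0.883 ± 0.17. Cell cycle genes went from -1.03 to -1.3 and antigen presentation genes from -0.841 to -0.736. B and plasma cell markers kept 77.6% at -0.668 ± 0.392, within 2 SE of 0. However, the mean log2 CPM of the atrial markers did not overlap between Ang II (6.227 to 6.999) and EHP-101 libraries (3.949 to 5.949). The adjustment thus rests on slopes within groups, Control replicate 2 included. Its cell cycle score was 0.92, against -0.12 and 0.03 in the other controls. The test cannot decide, and the tissue explanation stays open for all these lists. A higher share of cardiomyocyte RNA would lower endothelial and smooth muscle markers as much, but the members lay -0.813 ± 0.173 below these markers. A lower number or activity of immune and dividing cells under EHP-101 may underlie the pattern and stays open as a hypothesis, as do differences between pieces of heart that neither test measures.

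Matrix genes were higher under EHP-101 than under losartan, by a mean log2 difference of 0.631 ± 0.243 (SE). The fit with the atrial score kept 84.8% of the difference, at 0.536 ± 0.165. That argues against atrial and epicardial tissue as the whole cause. The collagens alone differed by 0.568 ± 0.352 without that score, already within 2 SE of 0. With it they kept 76.9%, at 0.437 ± 0.258, so for them the tissue explanation stays open. A lower share of RNA from fibroblasts in general under losartan would move fibroblast markers as far. The matrix genes exceeded these markers by 0.458 ± 0.137, and the collagens alone by 0.395 ± 0.219, within 2 SE of 0. Myofibroblast markers, some of which are matrix genes themselves, were not part of that test. Their mean score was 0.38 under EHP-101 and -0.31 under losartan, so a lower share of myofibroblast RNA stays open. Different effects of the treatments on matrix expression were not tested apart from these and stay open. For EHP-101 against Ang II alone, the mean of the matricellular genes went from -0.29 ± 0.289 to 0.0741 ± 0.236 once the atrial score was held fixed, so that smaller difference cannot be separated here from the tissue sampled.

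Oxidative phosphorylation and ribosomal protein genes were higher in Control replicate 2, with scores of 0.86 and 0.85. A candidate explanation is a bias of that library by gene length. Over 15217 genes outside these lists, its deviation from the other control libraries had a Spearman rho of -0.426 with gene length, across genes that are not independent replicates. Libraries of the other groups had -0.136 to 0.147. Control replicates 1 and 3 had 0.322 and 0.42, but their deviations are taken from a mean that includes Control replicate 2 and so mirror it. Less atrial and epicardial tissue stays open. In the 3 other libraries with an atrial score of -1 or less, the highest oxidative phosphorylation score was 0.06. All 3 came from mice given Ang II and a treatment, so tissue and treatment cannot be told apart in them. Their epicardial scores of -1.05, -0.9 and -0.76 also lay above the -1.92 of Control replicate 2. No biological explanation was tested.

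Splits of the 6 samples of a comparison into other groups of 3 number 10 with the real one, too few for a share under 0.05. For Ang II against control, 1 split called as many genes as the real 83, and the highest other called 0. For EHP-101 against control, 1 split reached the real 61, and the highest other called 0. For the counts of 0 genes, all 10 splits were as large: the highest other called 0 for EHP-101 and for losartan against Ang II, 15 for EHP-101 against losartan and 19 for losartan against control. The 15 came from EHP-101 replicates 1 and 2 with losartan replicate 1 against the rest, and the 19 from Control replicates 1 and 3 with losartan replicate 2 against the rest, so samples can also divide across the groups, for a reason that was not tested. Ang II genes called in the opposite direction numbered 0 in all 10 splits for each treatment. Lists past camera numbered 28 for Ang II against control, with 27 in the highest other split and 1 split as large. For EHP-101 against Ang II they numbered 28, with 24 in the highest other and 1 as large. For losartan against Ang II they numbered 26, with 28 in the highest other and 2 as large, and for EHP-101 against losartan 20, with 19 and 1. Splits that mixed the groups thus passed nearly as many lists, or more. A small camera p-value at the preset correlation is therefore not by itself evidence of a difference between the groups.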
